A study of Mus musculus with 15 samples.

How the data were processed

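RNA of primary hepatocytes from male C57BL/6 mice had been labelled with biotin and hybridised to 15 Affymetrix arrays, 3 for each of 5 groups: freshly isolated cells (t0), and cells cultured for 4 h or 24 h either in a tissue culture dish (TCD), where they form a monolayer, or in a rotating wall vessel (RWV), where they form aggregates. The replicates are independent biological replicates per the labels. The number of arrays limits the precision: each group mean rests on 3 values, and the spread was estimated with 10 residual degrees of freedom.

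The deposited values were log2 signals that the authors had made with GCRMA, a method that corrects for background by probe sequence, normalises between arrays and summarises probe sets; its version is not given in the sources used here. In each of the 45101 probe sets the median of the 3 fresh arrays was 0 (tolerance 1e-06), so the fresh median had been subtracted from every probe set. The values, from -11.2 to 13.6, are therefore changes from fresh cells, and the absolute signal of a gene could not be read from them. The subtraction was read from the values themselves, and the base of the logarithm was taken from GCRMA's scale.

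Of the probe sets, 64 were array controls, 34945 carried 1 gene symbol, 932 carried several and 9160 carried none in the platform annotation, which may be older than current gene names. The symbols were matched to current ones through a table of mouse genes (34741 probe sets had their Entrez number in it). Probe sets with 1 symbol were used. A minimum signal of 4 in 3 arrays, the probe set with the highest mean for each gene, and a minimum mean of 6 for named genes had been fixed before the data were examined, together with the comparisons, the gene lists and the tests. None of these level-based choices could be applied to values that hold no level. The substitutes were chosen after the data had been seen. A probe set counted as background when its values followed the array medians of the 20% least variable probe sets (correlation above 0.8) with an SD below 0.5. This removed 19609 probe sets, 12850 of them with 1 symbol. For each gene the remaining probe set with the largest SD was taken, which left 12422 of 18193 genes. For 5611 of them more than 1 probe set had remained.

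Group means were compared with limma 3.58.1 (lmFit, contrasts.fit and eBayes, no trend, not robust) in R 4.3.3 with the data.table package (version 1.17.8), all 15 arrays in 1 fit. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within a comparison, and the number of called genes that differed at least 2-fold is given beside the count. Errors after ± are standard errors from this fit unless an SD is named, except that those of medians or control probe sets taken per array come from the SDs of the 2 groups compared. The comparisons were RWV against TCD at 4 h and at 24 h, the difference between these 2 differences (the interaction), each cultured group against fresh cells, and 24 h against 4 h within each vessel. The distance of an array from fresh cells was the root mean square, over the genes tested, of its log2 change from the mean of the fresh arrays. RWV and TCD arrays were compared on it with a two-sided exact permutation test, for which 3 against 3 arrays allow no p below 0.1.

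Gene lists written from general knowledge, 34 for pathways and liver functions and 7 for markers of other cell types, were tested in all comparisons except 24 h against 4 h with camera of limma, which asks whether the members of a list shifted relative to the other genes. The preset correlation between genes was 0.01, and p was adjusted over the 41 lists of a comparison. Members called within a list were counted over all genes and also adjusted over the list alone. Camera was repeated with a correlation estimated for each list, and fry, a rotation test of whether the members of a list move on balance 1 way, was run beside it. The named genes followed a rule: the 10 largest changes each way among called genes whose 3 values in 1 group all lay above those of the other (5 each way for the interaction and the comparisons with fresh cells), up to 4 called members of each list with the largest changes, or the member with the smallest p, and Hnf4a, Cebpa, Alb, Cyp3a11, Cyp7a1, Actb and Vim in the RWV to TCD comparisons. A named gene with probe sets called in opposite directions is said to be uncertain. The values of a named gene are those of 1 probe set, and its other probe sets were not always called.

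The replicate numbers recur in every group, and the labels do not say what they mark. After group means had been subtracted, all 15 arrays were closest to an array of their own number, and in 5 of 10 pairs of groups all 3 correlations between arrays of 1 number exceeded 0.1. This pairing comes from the data, so the replicate block was kept as an alternative and not used in the fit. The other alternatives were no filter, the mean of a gene's probe sets, leaving out probe sets of shared sequence, only the arrays of the groups compared, array weights, a trended or a robust variance prior, centring each array on the median of the genes tested or on reference genes (10 of 12 listed were measured), an adjusted p below 0.01, 1 minus Spearman's correlation as the distance, and each array left out in turn. A stricter filter (SD at least 0.3, 9117 genes) and a background correlation above 0.9 were added after the data had been seen. The planned level filter of 6 could not be run. Each reference gene was read by its probe set with the largest SD, and 3 of the 10 measured are ribosomal protein genes. Where the median of all genes lies away from 0 after this centring, the reference genes had themselves shifted relative to the others. Centring on them is therefore not a neutral scale.

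The fit was tested on simulated data by drawing 15 arrays with each gene's own spread and adding known changes to the RWV arrays of 24 h. Of 100 genes changed by 1 log2 unit 68 were called, and of 100 changed by 2 units 88 were called, 0 of them with the wrong sign; 13 unchanged genes were called, and 1 in the comparison at 4 h, where nothing had been changed. A list of 30 genes shifted by 0.5 had a camera p of 5.66e-21, and an unshifted list 0.587. The genes were drawn independently of each other and the arrays without pairing. The simulation therefore does not test camera where the genes of a list are correlated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.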

Results

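The series set monolayers of primary mouse hepatocytes against aggregates of the same cells. Gene expression was measured on 15 arrays, 3 for each of 5 groups. The groups were freshly isolated hepatocytes (t0), cells kept for 4 h or 24 h in a tissue culture dish (TCD, monolayer), and cells kept for 4 h or 24 h in a rotating wall vessel (RWV, aggregates). Values are log2 changes from the median of the fresh arrays, and 12422 genes were tested. The number of arrays, 3 per group, limits the precision. Because the signal level itself was not kept, a very large fold against a group near the background rests on the floor that GCRMA sets for weak signals. The median of all probe sets other than controls lay between -0.077 and 0.077 on every array. Because 19609 of these counted as background, this does not show that the expressed genes were centred alike. Whether the total amount of RNA per cell differed between groups is not known from the arrays.

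Time in culture separated the arrays more than the vessel did. The first principal component held 59.99% of the variance and set the 24 h arrays apart from the fresh and 4 h arrays. The second held 17.6% and set the fresh arrays apart from the 4 h arrays. After 4 h the distance from fresh cells was alike in both vessels, 1.03 ± 0.058 (SD, n = 3) log2 units in RWV and 1.04 ± 0.072 (SD, n = 3) in TCD (two-sided exact permutation p = 0.9). After 24 h all 3 RWV arrays (1.37 to 1.501) lay closer to fresh cells than all 3 TCD arrays (1.66 to 1.74). The means were 1.46 ± 0.078 and 1.70 ± 0.040 (SD, n = 3), and the two-sided exact permutation p was 0.1, the smallest that 3 against 3 arrays can give. The other planned measure, 1 minus Spearman's correlation with the mean of the fresh arrays, could not test this separation. Because the fresh median had been subtracted, that mean holds little but the spread among the fresh arrays. By that measure the means were 0.9907 in RWV and 0.9974 in TCD, and the exact permutation p was 0.2. One array stood out by its quality. In replicate 2 of TCD at 4 h the 18 hybridisation control probe sets had a median of 1.08, against -0.73 to 0.18 in the other 14 arrays, and its array weight was 0.171.

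**Figure D1:**
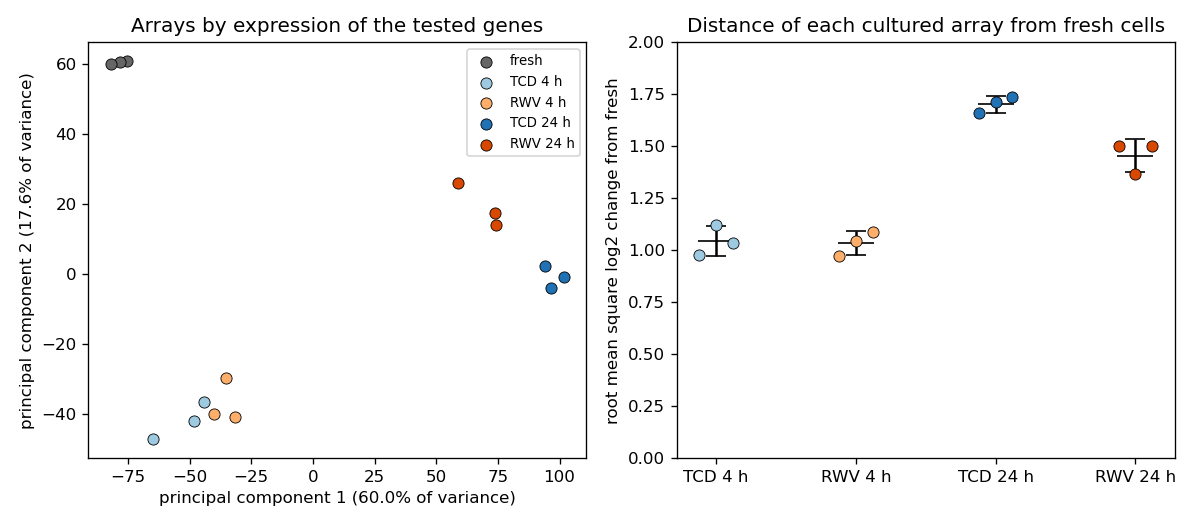
Left, the 15 arrays on the first 2 principal components (59.99% and 17.6% of the variance, axes in component scores); right, the root mean square log2 change from fresh cells of each cultured array (points), with the mean and SD of each group of 3 (bars). At 24 h the RWV arrays lie at 1.37 to 1.501 and the TCD arrays at 1.66 to 1.74, while at 4 h the groups overlap.

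The comparison of the vessels at 4 h asked how aggregates and monolayers differed early in culture. Aggregates had more mRNA of Fgf21, a hormone that hepatocytes secrete under metabolic stress, by 5.06 ± 0.611 log2 units (n = 3 per group, adjusted p = 0.00102), and of Txnip, which restrains glucose uptake, by 4.14 ± 0.753 (adjusted p = 0.00843). They had less mRNA of Ackr3, a scavenger receptor for the chemokine Cxcl12 (-3.30 ± 0.315, adjusted p = 0.000327), of the glucose transporter Slc2a1 (-2.13 ± 0.385, adjusted p = 0.00815), of the glycolytic enzyme Pkm (-2.14 ± 0.298, adjusted p = 0.00213) and of the intermediate filament gene Vim (-2.69 ± 0.571, adjusted p = 0.0174). The hepatocyte regulators Hnf4a (0.34, adjusted p = 0.446) and Cebpa (0.55, adjusted p = 0.097) were not called, nor were Alb (0.03), Cyp3a11 (-0.00), Cyp7a1 (-0.83) and Actb (0.00). Whether the signal of Alb was near the ceiling of the arrays is not known.

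Genes of hypoxia and glycolysis were the group with the clearest shift at 4 h. Of 31 measured members 9 were lower in RWV, 0 were higher and 22 were not called (15 lower when adjusted over the list alone). Their median was -0.82 (camera adjusted p = 1.54e-11, adjusted p = 0.356 with an estimated correlation). Beside Slc2a1 and Pkm they included Hk2, the hexokinase of growing cells (-2.85 ± 0.679), and the oxidase of the endoplasmic reticulum Ero1a (-1.87 ± 0.330). Genes of ribosome biogenesis and translation shifted up, with a median of 0.41 (camera adjusted p = 3.7e-06, adjusted p = 0.554 with an estimated correlation). Of 35 measured, 2 were higher and 0 lower (8 and 0 when adjusted over the list alone), namely Gar1 (0.55 ± 0.111) and Nop56 (0.97 ± 0.238). Immediate early genes, which respond first to stimulation, shifted down, with a median of -0.29 (camera adjusted p = 0.00158, adjusted p = 0.554 with an estimated correlation). Here 1 was higher and 2 were lower of 32 (1 and 5 when adjusted over the list alone). The lower ones were Fos (-1.79 ± 0.318) and Btg2 (-2.63 ± 0.331), and the higher one was Dusp4 (0.80).

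Smaller shifts went down in 2 further lists at 4 h. The actin and tubulin cytoskeleton had 0 genes higher and 2 lower of 45 (3 lower when adjusted over the list alone) and a median of -0.08 (camera adjusted p = 0.0323, adjusted p = 0.589 with an estimated correlation). Periportal genes, which are active around the portal vein, had 0 of 21 called and a median of -0.18 (camera adjusted p = 0.0421, adjusted p = 0.541 with an estimated correlation). These medians are of the order of the background of the arrays, which lay at -0.065 to -0.017 in RWV and at 0.019 to 0.066 in TCD. The cytoskeleton lost its call without TCD replicate 2 (adjusted p = 0.0914), TCD replicate 3 (0.0677) or RWV replicate 2 (0.0507). Periportal genes lost theirs without TCD replicate 2 (0.114), TCD replicate 3 (0.0956), RWV replicate 2 (0.0541) or RWV replicate 3 (0.057). With no background filter both lists turned up against the other genes, and immediate early genes lost their call (adjusted p = 0.552).

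In lists that did not shift as a whole at 4 h, single genes were called. Enzymes of fatty acid synthesis were higher in RWV, with Acly at 1.65 ± 0.287 and Fasn at 2.02 ± 0.505 (2 of 22 lipogenic genes, 3 when adjusted over the list alone). So were genes of the oxidative stress response such as Pgd (1.51 ± 0.223) and Cbr3 (2.61 ± 0.539), with 3 of 31 higher and a camera adjusted p of 0.0785. Atf5 (0.98 ± 0.155), Psat1 (1.08 ± 0.247) and Phgdh (3.01 ± 0.759) of the unfolded protein and amino acid response were higher and Ero1a was lower (4 and 1 of 34, adjusted p = 0.658). Foxa2, a pioneer factor of liver genes, was higher (1.61 ± 0.265, adjusted p = 0.00492), while Nr3c1 of the same list was lower (-0.94 ± 0.254, adjusted p = 0.0489). Only 1 of the 6 probe sets of Nr3c1 off the background was called. Fhl2, a target of SRF, was lower (-1.56 ± 0.307), as was the tissue factor gene F3 (-2.75 ± 0.556). Tmsb10 was lower (-2.37 ± 0.337), with 3 of its 5 probe sets called lower, but without probe sets of shared sequence its adjusted p was 0.383.

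In limma, 766 genes were called at 4 h, 683 higher and 83 lower in RWV, and 458 of them differed at least 2-fold (413 higher, 45 lower). With no background filter the split turned, to 1332 higher and 5596 lower, while of the genes that differed at least 2-fold 570 were higher and 71 lower. The count depended on the other groups in the fit and on single arrays. With only the 6 arrays compared, 109 genes were called (86 higher, 23 lower). Of 43 called genes named by the rule, only Zfc3h1, Foxa2, Fos, Pkm and Slc2a1 kept their call in every alternative. Ackr3 kept it wherever it was measured. Its 1 probe set off the background is of shared sequence, so it was not tested without such probe sets. Without RWV replicate 1, 2 or 3 the counts were 497, 458 and 390, and without TCD replicate 2 it was 506 (420 higher, 86 lower). Hk2 lost its call without TCD replicate 3 (adjusted p = 0.0661), RWV replicate 1 (0.0978) or RWV replicate 2 (0.0918), and Vim without RWV replicate 2 (0.0662). The call of F3 ended without RWV replicate 1 (0.0549) or 2 (0.0528), and that of Cbr3 without RWV replicate 1 (0.0522) or 3 (0.0672). Centred on reference genes, which lowered the median of all genes to -0.22, the split was 434 higher and 356 lower. Under that centring Fasn (0.0531) and Gar1 (0.109) lost their call.

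The comparison at 24 h asked how the vessels differed once the cultures were established. Aggregates had more mRNA of Hnf4a (1.37 ± 0.228, n = 3 per group, adjusted p = 0.0015) and Cebpa (1.37 ± 0.176, adjusted p = 0.000276), master regulators of hepatocyte genes, though both had fallen from fresh cells in both vessels. They had far less mRNA of Ccn2, a matrix protein gene driven by YAP and TGF-beta (-6.45 ± 0.622, adjusted p = 3.35e-05). Energy genes lower in RWV were Hk1 (-5.77 ± 0.446) and the lactate exporter gene Slc16a3 (-5.24 ± 0.202, adjusted p = 1.57e-08). Structural ones were the collagen-modifying enzyme gene Plod2 (-5.92 ± 0.410) and the actin filament genes Acta1 (-5.44 ± 0.310) and Tpm2 (-5.22 ± 0.324). They had far more mRNA of Cyp1a1, a monooxygenase induced through the aryl hydrocarbon receptor (6.20 ± 0.424, adjusted p = 2.1e-06), of Fgf21 (5.80 ± 0.611), of the bile acid conjugating enzyme Baat (4.43 ± 0.214) and of the leptin receptor Lepr (4.38 ± 0.339). Alb (-0.09), Cyp3a11 (-0.15), Cyp7a1 (-0.28) and Actb (-0.27) were not called. Alb stayed near fresh cells (-0.06 in TCD and -0.15 in RWV), while Cyp7a1 was far below them (-7.96 and -8.24). Because no signal level was kept, a ceiling for Alb or a floor for Cyp7a1 could hide a difference.

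Liver transcription factors were higher in RWV at 24 h, with 14 of 28 measured members higher, 0 lower and 14 not called (16 higher when adjusted over the list alone). Their median was 1.19 (camera adjusted p = 1.42e-08, adjusted p = 0.0616 with an estimated correlation). At that time the gap between the 3' and 5' control probe sets of Actb, a sign of RNA quality, was larger in RWV than in TCD by 0.21 ± 0.0149 (n = 3, two-sided exact permutation p = 0.1), while that of Gapdh differed by -0.02 ± 0.0109 (p = 0.1). Nr5a2 was at 2.38 ± 0.354, Esr1 at 2.88 ± 0.570 and Mlxipl, the carbohydrate response factor, at 2.41 ± 0.150. Genes of gluconeogenesis and glycogen shifted up as well, 12 higher and 2 lower of 22 (13 and 3 when adjusted over the list alone). The median was 0.83 (camera adjusted p = 1.87e-06, adjusted p = 0.0272 with an estimated correlation). Glycogen synthase Gys2 was higher (2.31 ± 0.288), as was Tkfc of fructose breakdown (2.90 ± 0.311). Pck1, the gluconeogenic enzyme under hormonal control, went the other way (-4.26 ± 0.347, adjusted p = 9.05e-06). In the oxidative stress response 13 genes were higher and 1 lower of 31 (16 and 1 when adjusted over the list alone). The median was 0.51 (camera adjusted p = 7.66e-08, adjusted p = 0.0272 with an estimated correlation), with Cbr3 at 3.70 ± 0.539, Gstm3 at 3.47 ± 0.347 and Mt1 at 2.68 ± 0.346.

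Several metabolic groups were higher in RWV at 24 h. Lipogenesis had 8 genes higher and 2 lower of 22 (12 and 2 when adjusted over the list alone) and a median of 0.75 (camera adjusted p = 9.43e-05, adjusted p = 0.264 with an estimated correlation). Acaca stood at 2.38 ± 0.204 and Elovl6 at 2.02 ± 0.342. The tricarboxylic acid cycle and respiratory chain had small changes, 8 higher and 1 lower of 39 (12 and 1 when adjusted over the list alone; median 0.18, camera adjusted p = 0.000531, adjusted p = 0.367 with an estimated correlation). Fatty acid oxidation had 11 higher and 4 lower of 28 (13 and 4 when adjusted over the list alone; median 0.39, camera adjusted p = 0.0224, adjusted p = 0.446 with an estimated correlation). Within it the nuclear receptor gene Ppara was higher (2.30 ± 0.506) and the fatty acid binding protein gene Fabp1 lower (-1.69 ± 0.217).

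Hepatocyte transporters had 9 higher and 2 lower of 30 (10 and 2 when adjusted over the list alone) and a median of 0.25 (camera adjusted p = 0.0224, adjusted p = 0.394 with an estimated correlation). Slco2b1 (1.85 ± 0.145) and Slc25a47 (1.87 ± 0.188) were higher and Slco1b2, which takes up bile acids and drugs, was lower (-2.37 ± 0.375). Conjugation enzymes passed narrowly, 13 higher and 6 lower of 35 (median 0.40, camera adjusted p = 0.0498, adjusted p = 0.446 with an estimated correlation). The proteasome had 4 higher and 1 lower of 31 (median 0.18, camera adjusted p = 0.00632, adjusted p = 0.357 with an estimated correlation). The heat shock response had 3 higher and 1 lower of 23 (median 0.37, camera adjusted p = 0.0331, adjusted p = 0.446 with an estimated correlation).

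Genes of glycolysis, the cytoskeleton and adhesion were lower in RWV at 24 h, when the gap of the Actb control probe sets differed by 0.21. Among 31 hypoxia and glycolysis genes 18 were lower and 0 higher (23 lower when adjusted over the list alone), with a median of -0.97 (camera adjusted p = 5.55e-13, adjusted p = 0.0616 with an estimated correlation). Beside Hk1 and Slc16a3, Hk2 stood at -3.65 ± 0.679, while Slc2a1 was no longer called (-1.13 ± 0.385, adjusted p = 0.0712). In the cytoskeleton list 1 gene was higher and 18 of 45 were lower (22 when adjusted over the list alone), with a median of -0.38 (camera adjusted p = 3.22e-08, adjusted p = 0.0616 with an estimated correlation). Moesin Msn (-4.15 ± 0.397), tubulin Tuba1a (-2.75 ± 0.325) and filamin Flna (-2.57 ± 0.268) were among them. Integrins and focal adhesion genes followed, 2 higher and 12 lower of 34 (3 and 13 when adjusted over the list alone; median -0.44, camera adjusted p = 0.000286, adjusted p = 0.237 with an estimated correlation). Itga3 was at -2.76 ± 0.207, Src at -2.92 ± 0.309 and Enah at -3.66 ± 0.451. YAP and SRF targets had 2 higher and 6 lower of 29 (2 and 7 when adjusted over the list alone; camera adjusted p = 0.0172, adjusted p = 0.0707 with an estimated correlation). Ankrd1 (-3.79 ± 0.168) and Fhl2 (-2.97 ± 0.307) were among the lower ones. The median of that list, -0.09, became 0.02 when arrays were centred on reference genes.

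Weaker shifts went down in RWV at 24 h in 4 further lists. Ribosome biogenesis had 0 higher and 2 lower of 35 (median -0.29, camera adjusted p = 0.00465, adjusted p = 0.446 with an estimated correlation), with Eif4e, the cap-binding factor, at -1.71 ± 0.358. Cholangiocyte markers had 0 higher and 3 lower of 8 (4 when adjusted over the list alone; median -0.57, camera adjusted p = 0.0223, adjusted p = 0.237 with an estimated correlation). Periportal genes had 2 higher and 6 lower of 21 (median -0.34, camera adjusted p = 0.0303, adjusted p = 0.237 with an estimated correlation). Progenitor and fetal liver genes had 1 higher and 5 lower of 17 (median -0.20, camera adjusted p = 0.0482, adjusted p = 0.237 with an estimated correlation). Krt19, a keratin gene of bile duct cells, was at -4.31 ± 0.456 and the claudin gene Cldn4 at -4.31 ± 0.521, while the fetal gene Afp was higher (1.64 ± 0.277).

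Other lists did not shift at 24 h although single members differed. Plasma proteins and apolipoproteins (5 higher and 2 lower of 31, camera adjusted p = 0.56), acute phase proteins (0 of 25, 0.521) and cytochromes P450 and phase I enzymes (5 and 3 of 37, 0.292) were not called. Nor were cholesterol synthesis (0 of 20, 0.367), NF-kB and chemokines (1 and 1 of 27, 0.673) or interferon-stimulated genes (2 and 3 of 29, 0.263). The circadian clock (1 and 1 of 22, 0.626) and the unfolded protein and amino acid response (1 and 2 of 34, 0.848) were balanced. Bile acid synthesis held opposite changes (6 and 4 of 20, 0.24), with Baat and Cyp8b1 (3.14 ± 0.490) higher and Akr1d1 (-2.85 ± 0.398) and Akr1c6 (-2.47 ± 0.212) lower. The urea cycle and amino acid catabolism had 8 higher and 10 lower of 39 (0.0867), with Gldc at 2.58 ± 0.501 and Hpd at -1.95 ± 0.259.

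Lists of matrix, growth and signalling came close at 24 h without passing. They were the extracellular matrix (2 higher and 7 lower of 31, camera adjusted p = 0.0581), TGF-beta and epithelial-mesenchymal transition (2 and 6 of 25, 0.0625) and immediate early genes (2 and 4 of 32, 0.0581). Cell cycle genes (0 and 3 of 32, 0.0735), p53 targets (0 and 1 of 22, 0.0541) and pericentral genes (4 and 5 of 23, 0.145) were not called either. Single genes in them were far lower in RWV, such as thrombospondin Thbs1 (-4.75 ± 0.539), Tgfb2 (-3.64 ± 0.377), cyclin Ccne2 (-2.07 ± 0.312) and Fosl2 (-2.21 ± 0.239). Among cell-cell junction genes (6 and 3 of 31, 0.558) the gap junction genes Gjb2 (3.03 ± 0.271) and Gjb1 (1.68 ± 0.213) were higher.

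In limma, 1890 genes were called at 24 h, 1038 higher and 852 lower in RWV, 931 of them at least 2-fold (482 higher, 449 lower). Centred on reference genes, which moved the median of all genes by 0.11, the split was 1473 higher and 681 lower. Without RWV replicate 2 of 24 h the count was 1234, and Vim (-2.39 ± 0.571) lost its call (adjusted p = 0.0644). Without that array conjugation enzymes (0.257), heat shock (0.0925), periportal genes (0.0699) and transporters (0.0699) no longer passed. Without TCD replicate 2 of 24 h, heat shock (0.0692), periportal genes (0.0574) and fatty acid oxidation (0.065) did not pass. Without RWV replicate 3 of 24 h fatty acid oxidation (0.0707) did not, and without TCD replicate 2 of 4 h periportal genes (0.0518) did not. Conjugation enzymes also failed without TCD replicate 1 (0.0707) or 3 (0.0728) of 24 h, TCD replicate 2 (0.0614) or RWV replicate 1 (0.0515), 2 (0.054) or 3 (0.0539) of 4 h, or t0 replicate 2 (0.0539). Progenitor genes failed without RWV replicate 1 (0.0912) or 2 (0.0837) or TCD replicate 3 (0.0728) of 24 h, TCD replicate 2 (0.0673) or 3 (0.0562) of 4 h, or t0 replicate 2 (0.0528) or 3 (0.0578).

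**Figure D2:**
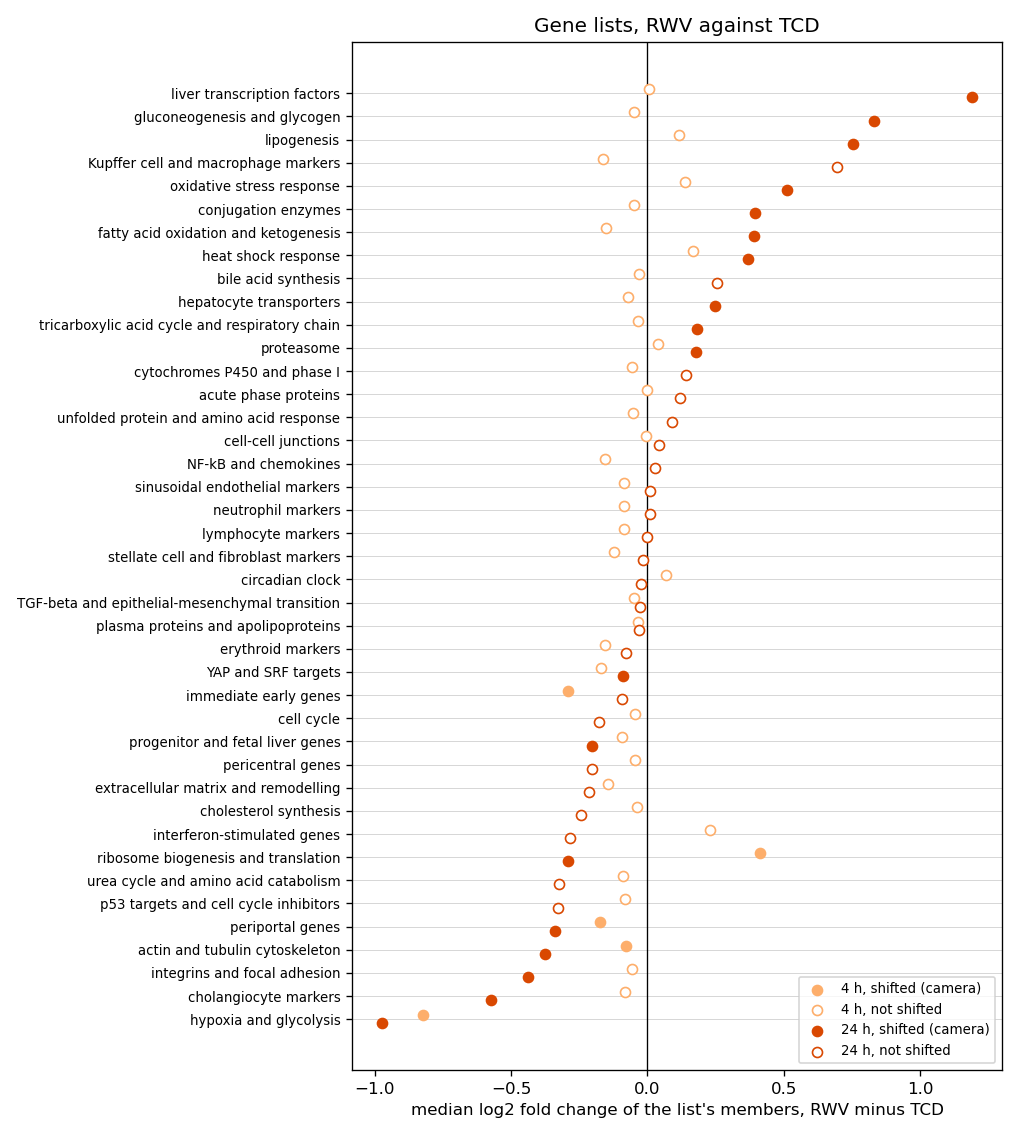
Median log2 fold change of each gene list, RWV minus TCD, at 4 h and at 24 h (3 arrays per group); filled points mark lists that camera found shifted relative to the other genes. Hypoxia and glycolysis genes lie lowest among the shifted lists at both times (-0.82 and -0.97) and liver transcription factors highest at 24 h (1.19), while the YAP and SRF targets at 24 h (-0.09) turn to 0.02 when arrays are centred on reference genes.

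**Figure D3:**
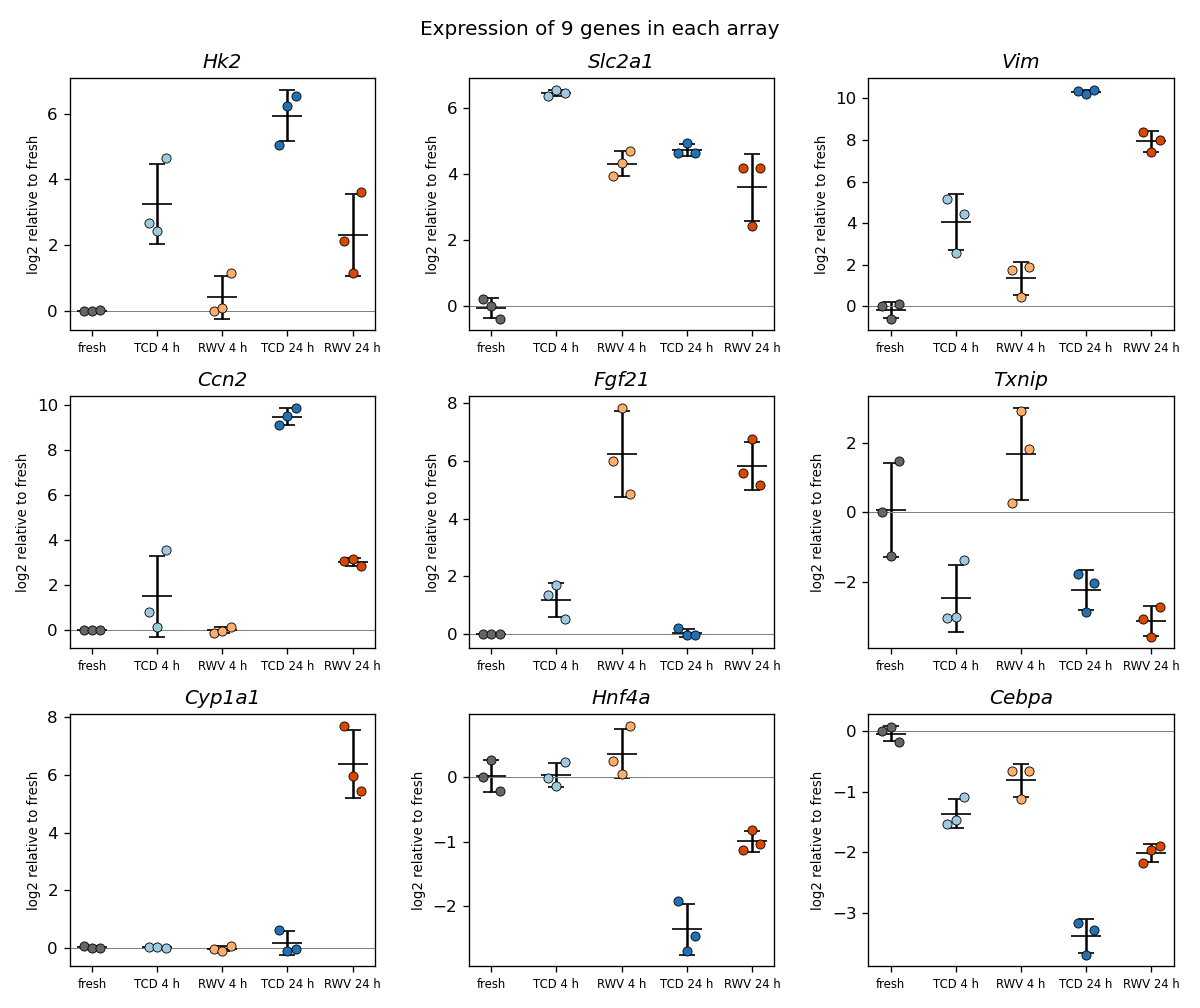
Log2 level relative to fresh cells of 9 genes on each of the 15 arrays (points), with the mean and SD of the 3 arrays of a group (bars). Hk2 and Vim are lower in RWV than in TCD at both times, Fgf21 is higher at both times, and Cyp1a1 is higher (6.20) and Ccn2 lower (-6.45) in RWV at 24 h.

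Whether the difference between the vessels changed with time was tested as an interaction. Cyp1a1 (6.25 ± 0.599, n = 3 per group, adjusted p = 0.000105), the phosphate transporter gene Slc17a3 (5.44 ± 0.451, adjusted p = 3.42e-05), N4bp2l1 (4.53 ± 0.593), Hykk (4.52 ± 0.858) and Baat (4.45 ± 0.303) moved up in RWV relative to TCD between 4 h and 24 h. Plod2 (-5.85 ± 0.580), Serpinb9g (-5.54 ± 0.370), Acta1 (-5.40 ± 0.438), Lce1f (-5.30 ± 1.15) and the stress gene Nupr1 (-5.14 ± 0.553) moved down. With a trended variance prior the adjusted p of Hykk was 0.2. Txnip, higher in RWV at 4 h, was not called at 24 h (-0.90 ± 0.753, adjusted p = 0.531), and its interaction was -5.04 ± 1.07 (adjusted p = 0.0102). No change with time was called for Fgf21 (0.74, adjusted p = 0.623), Vim (0.31, adjusted p = 0.841) or Hk2 (-0.80, adjusted p = 0.633). Nor was one called for Slc2a1 (1.003, adjusted p = 0.261), Hnf4a (1.03, adjusted p = 0.0557) or Cebpa (0.82, adjusted p = 0.0503).

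Groups moved apart in the same sense. Relative to TCD, RWV gained liver transcription factors (9 higher and 0 lower of 28), with a median of 1.04 (camera adjusted p = 3.2e-06, adjusted p = 0.33 with an estimated correlation). It also gained gluconeogenesis and glycogen (12 and 2 of 22), with a median of 0.74 (1.83e-05, 0.0852 with an estimated correlation), and the oxidative stress response (7 and 0 of 31), with 0.27 (0.00756, 0.413 with an estimated correlation). Smaller gains were in fatty acid oxidation (8 and 2 of 28, median 0.60, adjusted p = 0.0108), lipogenesis (3 and 1 of 22, 0.40, 0.0108) and transporters (6 and 2 of 30, 0.33, 0.0108), each with an adjusted p of 0.588 with an estimated correlation. So were those in conjugation enzymes (7 and 1 of 35, 0.35, 0.0241), the tricarboxylic acid cycle (7 and 1 of 39, 0.21, 0.00024) and the proteasome (1 and 0 of 31, 0.16, 0.035), again with 0.588 each. Examples were Mttp (2.16 ± 0.290), Mlxipl (2.05 ± 0.213), Nqo1 (2.15 ± 0.377) and Ugt2b5 (1.16 ± 0.165). RWV lost ribosome biogenesis (0 higher and 7 lower of 35, median -0.58, camera adjusted p = 2.89e-06), integrins (1 and 8 of 34, -0.35, 0.0181) and the cytoskeleton (1 and 8 of 45, -0.33, 0.0108), each with 0.588 with an estimated correlation. Rrp9 was at -1.17 ± 0.232, Itga3 at -2.70 ± 0.292 and Msn at -4.10 ± 0.561. The shift of hypoxia and glycolysis genes did not change detectably with time (0 higher and 2 lower of 31, -0.36, adjusted p = 0.13).

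In limma, 1573 genes had a called interaction, 613 up and 960 down, 1102 of them at least 2-fold (391 up, 711 down). With no background filter the split turned to 2043 up and 1104 down. It also turned under reference-gene centring, which moved the median of all genes by 0.32 and gave 1728 up and 622 down, so the direction of the whole is set by the scaling. Under that centring the medians of the cytoskeleton (-0.02) and integrins (-0.03) shrank to almost 0. Both still passed relative to the other genes (camera adjusted p = 0.0201 and 0.00639). Conjugation enzymes (adjusted p = 0.0922), transporters (0.064), lipogenesis (0.0922) and Kupffer cell markers (0.0922) did not pass. Single arrays decided several lists. Conjugation enzymes did not pass without TCD replicate 2 of 4 h (adjusted p = 0.103) or RWV replicate 2 of 24 h (0.15), nor lipogenesis without TCD replicate 2 (0.0873) or RWV replicate 1 (0.0578) of 4 h. The cytoskeleton and integrins did not pass without RWV replicate 2 of 24 h (0.0563 for both), and the proteasome failed without TCD replicate 3 of 4 h (0.0656) or TCD replicate 2 (0.0823) or 3 (0.071) or RWV replicate 1 (0.0735) or 2 (0.0681) of 24 h.

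The comparisons with fresh cells asked what culture itself changed. At 4 h in TCD the largest rises were in Sprr1a (10.56 ± 0.402 log2 units, n = 3 per group, adjusted p = 6.63e-09), Anxa2 (9.13 ± 0.306), the vasodilator gene Adm (9.10 ± 0.824) and the injury response factor Klf6 (8.42 ± 0.203). In RWV they were in Sprr1a (10.62 ± 0.402), the serine synthesis gene Psat1 (8.81 ± 0.247), Klf6 (8.49 ± 0.203), Il1rn (8.29 ± 0.539) and the endotoxin co-receptor Cd14 (8.09 ± 0.290). The insulin receptor substrate Irs1 fell in TCD (-5.22 ± 0.578), and Id2 fell in TCD (-5.68 ± 0.560) and in RWV (-5.10 ± 0.560). Klf15, a regulator of amino acid breakdown, fell in TCD (-4.33 ± 0.437) and RWV (-3.59 ± 0.437). Pde4b was also among the largest falls in both, but its probe sets were called in opposite directions, so it is uncertain. Tmsb10 rose in both, but only with probe sets of shared sequence included. In TCD 3 of its 5 probe sets were called higher and 0 lower.

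Ribosome biogenesis rose together in both vessels by 4 h. Of 35 genes 24 were higher in TCD and 31 in RWV, and 0 were lower in either (median 0.91 and 1.30, camera adjusted p = 1.06e-15 and 6.26e-20, 0.116 and 0.192 with an estimated correlation). Eif4e (6.14 ± 0.358 and 6.59 ± 0.358) and Gar1 (2.41 ± 0.111 and 2.96 ± 0.111) were examples. Hypoxia and glycolysis genes rose in TCD, 22 of 31 higher and 0 lower, with a median of 1.90 (camera adjusted p = 1.39e-16, 0.0624 with an estimated correlation). In RWV 17 were higher and 0 lower, with a median of 0.87 (1.96e-06, 0.297 with an estimated correlation). Ankrd37 (6.90 ± 0.599 and 5.38 ± 0.599) and Slc2a1 (6.50 ± 0.385 and 4.37 ± 0.385) rose in both. The cytoskeleton rose in TCD, 17 higher and 3 lower of 45, with a median of 0.52 (camera adjusted p = 3.96e-09, 0.0624 with an estimated correlation). In RWV 16 were higher and 2 lower, with a median of 0.30 (4.28e-05, 0.274 with an estimated correlation) that became -0.08 under reference-gene centring. Tubb6 (6.60 ± 0.574 and 6.20 ± 0.574) and Tpm4 (4.16 ± 0.186 and 3.48 ± 0.186) were among them.

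Genes of first response and inflammation were higher at 4 h. For immediate early genes 15 were higher and 7 lower of 32 in TCD, and 14 and 9 in RWV (median 1.10 and 0.49, camera adjusted p = 4.24e-05 and 0.0221, 0.159 and 0.469 with an estimated correlation). For NF-kB and chemokine genes 12 and 4 of 27 were called in TCD and 10 and 5 in RWV (0.71 and 0.67, 0.000306 and 0.0117, 0.322 and 0.469 with an estimated correlation). For interferon-stimulated genes 6 and 1 of 29 were called in TCD and 10 and 1 in RWV (0.67 and 0.76, 0.000604 and 0.00242, 0.509 and 0.469 with an estimated correlation). Fosl1 (6.03 ± 0.405 and 5.94 ± 0.405), Icam1 (5.30 ± 0.617 and 5.24 ± 0.617) and Isg20 (4.05 ± 0.269 and 4.16 ± 0.269) were examples. Acute phase proteins shifted up, 9 and 2 of 25 in TCD and 8 and 1 in RWV (0.27 and 0.30, 0.000306 and 0.00126, 0.309 and 0.468 with an estimated correlation). The unfolded protein and amino acid response did too, 13 and 1 of 34 in TCD and 14 and 2 in RWV (0.12 and 0.35, 0.000141 and 0.00115, 0.228 and 0.375 with an estimated correlation). So did the oxidative stress response, 8 and 2 of 31 in TCD and 11 and 1 in RWV (0.04 and 0.21, 0.0496 and 0.00713, 0.309 and 0.274 with an estimated correlation). Ddit3 (6.11 ± 0.233 and 6.41 ± 0.233) and Srxn1 (5.35 ± 0.203 and 5.89 ± 0.203) rose in both. Under reference-gene centring the medians turned negative for acute phase proteins in RWV (-0.08), for the unfolded protein response in TCD (-0.06) and RWV (-0.03) and for oxidative stress in TCD (-0.13) and RWV (-0.17). The oxidative stress call in TCD ended without any array but TCD replicate 1 of 4 h and t0 replicate 3 (0.051 to 0.0912). The unfolded protein median also turned without TCD replicate 2 (-0.01) in TCD and without RWV replicate 3 (-0.02) in RWV.

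Some lists were called at 4 h in TCD but not in RWV. The p53 targets had 9 higher and 4 lower of 22 (median 0.76, camera adjusted p = 0.00276, 0.0624 with an estimated correlation), with Mdm2 at 2.90 ± 0.178. The extracellular matrix had 8 and 1 of 31 (0.08, 0.00276, 0.174 with an estimated correlation), with Lgals3 at 7.88 ± 0.685. Integrins had 7 and 2 of 34 (0.11, 0.00928, 0.352 with an estimated correlation), and the circadian clock had 8 and 3 of 22 (0.80, 0.0178, 0.392 with an estimated correlation). YAP and SRF targets had 6 and 4 of 29 (0.08, 0.0487, 0.159 with an estimated correlation). The medians of the extracellular matrix (-0.09), integrins (-0.06) and YAP and SRF targets (-0.09) turned under reference-gene centring, and the clock did not pass without t0 replicate 3 (0.0812). YAP and SRF targets did not pass without TCD replicate 2 (0.115) or RWV replicate 1 (0.0538) of 4 h, RWV replicate 1 of 24 h (0.0532), or t0 replicate 1 (0.0845) or 2 (0.059). Of these 5 lists none was called between the vessels at 4 h, where the adjusted p of the YAP and SRF targets was 0.0612. TGF-beta genes were called in TCD (10 and 3 of 25, median 0.18, 0.0105, 0.294 with an estimated correlation) and in RWV (8 and 2, 0.12, 0.0342, 0.468 with an estimated correlation). In RWV their median was -0.26 under reference-gene centring, and they did not pass without RWV replicate 3 (median -0.02, adjusted p = 0.0914) or t0 replicate 2 (0.0648).

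Hepatocyte genes had begun to fall by 4 h. Liver transcription factors were lower in TCD, 2 higher and 12 lower of 28, with a median of -0.81 (camera adjusted p = 0.00276, 0.294 with an estimated correlation). In RWV 2 were higher and 14 lower, with a median of -0.83 (0.00931, 0.468 with an estimated correlation). Tbx3 was at -4.23 ± 0.396 and -4.05 ± 0.396 and Ppara at -2.41 ± 0.506 and -2.53 ± 0.506. Bile acid synthesis was lower, 0 and 4 of 20 in TCD and 0 and 8 in RWV (-0.36 in both, 0.0496 and 0.0275, 0.294 and 0.309 with an estimated correlation). Pericentral genes were lower, 0 and 6 of 23 in TCD and 1 and 6 in RWV (-0.22 and -0.29, 0.0382 and 0.0126, 0.159 and 0.192 with an estimated correlation). In RWV the call also reached the urea cycle (0 and 7 of 39, -0.35, 0.0111) and cytochromes P450 (0 and 6 of 37, -0.29, 0.0342), with an adjusted p of 0.468 each with an estimated correlation. It reached the tricarboxylic acid cycle (0 and 10 of 39, -0.19, 0.00969), fatty acid oxidation (3 and 8 of 28, -0.48, 0.0323) and conjugation enzymes (0 and 8 of 35, -0.33, 0.0286), with 0.469 each with an estimated correlation. None of these 5 lists was called between the vessels at 4 h. Ass1 (-1.58 ± 0.334) and Otc (-1.55 ± 0.338) of the urea cycle, Ndufs1 (-0.54 ± 0.115) and Cpt2 (-1.03 ± 0.178) were lower in RWV. The P450 call did not pass without RWV replicate 1 (0.0707), t0 replicate 2 (0.0704) or t0 replicate 3 (0.102). Fatty acid oxidation did not pass without RWV replicate 2 (0.0892), t0 replicate 2 (0.0587) or t0 replicate 3 (0.0899), and conjugation without t0 replicate 2 (0.0587) or 3 (0.102). In TCD bile acid synthesis did not pass without TCD replicate 1 (0.133) or 3 (0.0734) or RWV replicate 1 (0.0538) of 4 h, TCD replicate 1 of 24 h (0.0508), or t0 replicate 1 (0.0519) or 2 (0.106). Pericentral genes did not pass there without TCD replicate 1 (0.0706) or 3 (0.0734) of 4 h or t0 replicate 1 (0.0519). Without t0 replicate 2 bile acid synthesis (0.0566) and the urea cycle (0.052) did not pass in RWV.

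In limma, 3164 genes were called at 4 h in TCD (1185 higher, 1979 lower; 1826 at least 2-fold, 802 higher and 1024 lower) and 3670 in RWV (1880 higher, 1790 lower; 2005 at least 2-fold, 1303 higher and 702 lower). With arrays centred on reference genes and the median of all genes at -0.22 in TCD and -0.45 in RWV, the splits were 1026 higher and 3293 lower in TCD and 1398 higher and 6510 lower in RWV, so how many genes rose or fell rests on the scaling. These medians mean that the reference genes had themselves risen relative to the other genes, so neither scaling is known to be right. With only the arrays compared, 1532 genes were called in TCD (705 higher, 827 lower). Without TCD replicate 2 of 4 h 2988 were called there (1469 higher, 1519 lower), and of those that differed at least 2-fold 963 were higher and 774 lower, so that this split turned.

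By 24 h the change from fresh cells had grown. Anxa2 (12.18 ± 0.306 in TCD, 11.19 ± 0.306 in RWV, n = 3 per group), Sprr1a (12.46 ± 0.402 and 11.25 ± 0.402), Lgals3 (12.02 ± 0.685 and 10.69 ± 0.685) and Vim (10.48 ± 0.571 and 8.09 ± 0.571) stood far above fresh cells. Cyp7a1, the first enzyme of bile acid synthesis, fell in both (-8.14 ± 0.505 and -8.42 ± 0.505). So did Upp2 (-8.31 ± 0.418 and -10.29 ± 0.418) and Pck1 (-6.78 ± 0.347 and -11.04 ± 0.347). Klf15 fell in TCD (-8.50 ± 0.437) and RWV (-5.03 ± 0.437), and Hnf4a in TCD (-2.39 ± 0.228) and RWV (-1.02 ± 0.228). Ccn2 rose in TCD (9.48 ± 0.622) and RWV (3.03 ± 0.622).

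Liver functions fell together in both vessels at 24 h. All 39 measured genes of the urea cycle and amino acid catabolism were lower in TCD and in RWV (median -3.31 and -3.32, camera adjusted p = 2.19e-18 and 6.61e-24, 0.00753 and 0.00285 with an estimated correlation). Tdo2 (-5.92 ± 0.304 and -6.64 ± 0.304) and Hal (-5.68 ± 0.528 and -7.93 ± 0.528) were among them. Of 20 bile acid synthesis genes 19 were lower in TCD and 20 in RWV (-2.60 and -2.14, 1.45e-10 and 6.42e-12, 0.0041 and 0.0024 with an estimated correlation). Of 37 cytochrome P450 and phase I genes 32 and 30 were lower and 0 and 2 higher (-1.95 and -1.80, 9.89e-13 and 1.36e-13, 0.0049 and 0.00285 with an estimated correlation). Cyp2u1 was at -4.81 ± 0.241 and -4.22 ± 0.241, while Cyp1a1 rose in RWV (6.35 ± 0.424). Liver transcription factors had 1 higher and 24 lower of 28 in TCD and 1 and 20 in RWV (-2.99 and -1.82, 2.94e-10 and 1.29e-07, 0.0216 and 0.0489 with an estimated correlation).

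Conjugation enzymes had 0 higher and 34 lower of 35 in TCD at 24 h and 2 and 26 in RWV (median -2.06 and -1.67, camera adjusted p = 2.38e-12 and 2.08e-09, 0.0197 and 0.0469 with an estimated correlation). Transporters had 3 and 25 of 30 and 2 and 22 (-3.01 and -2.53, 2.94e-10 and 2.08e-09, 0.0216 and 0.0362 with an estimated correlation). Plasma proteins had 0 and 28 of 31 and 0 and 27 (-0.91 and -0.65, 2.94e-10 and 7.03e-12, 0.0406 and 0.0362 with an estimated correlation). Pericentral genes had 0 and 22 of 23 and 0 and 23 (-1.95 and -2.30, 1.45e-10 and 1.7e-13, 0.000945 and 0.000275 with an estimated correlation). Periportal genes had 2 and 18 of 21 and 2 and 17 (-2.23 and -2.91, 1.96e-07 and 1.97e-09, 0.00845 and 0.00293 with an estimated correlation), with Aldh1b1 at -5.92 ± 0.259 and -5.65 ± 0.259.

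Fuel metabolism fell too. Fatty acid oxidation had 2 higher and 25 lower of 28 in each vessel (median -2.16 in TCD and -2.04 in RWV, camera adjusted p = 1.45e-10 and 1.05e-11, 0.0526 and 0.0489 with an estimated correlation). The tricarboxylic acid cycle and respiratory chain had 2 and 34 of 39 in TCD and 2 and 31 in RWV (-0.76 and -0.52, 3.68e-10 and 1.58e-09, 0.0672 and 0.0753 with an estimated correlation). Gluconeogenesis and glycogen had 2 and 17 of 22 in TCD and 4 and 14 in RWV (-1.47 and -0.76, 2.95e-06 and 0.00439, 0.0134 and 0.0704 with an estimated correlation). Idh2 stood at -2.44 ± 0.183 and -1.90 ± 0.183, and G6pc at -5.96 ± 0.440 and -4.10 ± 0.440. Lipogenesis was called in TCD (2 and 13 of 22, -1.05, 0.0035, 0.324 with an estimated correlation) and also between the vessels. Cholesterol synthesis was called in RWV (1 and 8 of 20, -0.61, 0.0156, 0.574 with an estimated correlation) but not between the vessels, and did not pass without t0 replicate 2 (adjusted p = 0.0755). With reference-gene centring gluconeogenesis in RWV (0.0638), lipogenesis in TCD (0.0658) and cholesterol synthesis in RWV (0.294) did not pass.

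The cytoskeleton rose with 35 of 45 genes higher and 2 lower in each vessel (median 2.29 in TCD and 1.40 in RWV, camera adjusted p = 1.49e-10 and 6.06e-09, 0.0192 and 0.0362 with an estimated correlation). Tagln2 (6.91 ± 0.707 and 7.06 ± 0.707), which binds actin, was among them. Integrins had 25 higher and 2 lower of 34 in TCD and 17 and 3 in RWV (1.90 and 0.79, 1.49e-05 and 0.00559, 0.102 and 0.309 with an estimated correlation), and their median in RWV was -0.07 under reference-gene centring. Hypoxia and glycolysis genes had 28 and 1 of 31 and 23 and 2 (3.50 and 2.03, 3.95e-10 and 6.96e-06, 0.0562 and 0.149 with an estimated correlation). Ribosome biogenesis had 33 and 0 of 35 in both (1.79 and 1.51, 1.49e-10 and 8.36e-11, 0.0865 and 0.0817 with an estimated correlation). The p53 targets had 14 and 3 of 22 and 12 and 4 (2.01 and 1.34, 0.0039 and 0.0156, 0.0239 and 0.0524 with an estimated correlation). Pkm (9.37 ± 0.298 and 7.89 ± 0.298), Itga6 (5.43 ± 0.405 and 5.62 ± 0.405), Phlda3 (5.88 ± 0.178 and 6.09 ± 0.178) and Gar1 (3.21 ± 0.111 and 2.86 ± 0.111) were examples. The proteasome was higher, 18 and 0 of 31 in TCD and 25 and 0 in RWV (0.44 and 0.64, 0.00195 and 1.48e-06, 0.206 and 0.0704 with an estimated correlation). Under reference-gene centring its median was -0.53 in TCD (adjusted p = 0.678) and -0.22 in RWV (0.222). In RWV the oxidative stress response was also called (20 and 6 of 31, 0.77, 0.0033, 0.0824 with an estimated correlation), with a median of -0.09 under that centring. The heat shock response was called there too (12 and 1 of 23, 0.88, 0.0114, 0.397 with an estimated correlation). Slc7a11 stood at 4.66 ± 0.361 and Hspa1a at 5.67 ± 0.864.

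In limma, 6981 genes were called after 24 h in TCD (4076 higher, 2905 lower; 4764 at least 2-fold, 2858 higher and 1906 lower) and 6203 in RWV (3817 higher, 2386 lower; 3939 at least 2-fold, 2465 higher and 1474 lower). With arrays centred on reference genes and the median of all genes at -0.98 and -0.85, the splits were 1864 higher and 7908 lower in TCD and 1556 higher and 7585 lower in RWV. With a correlation estimated from the data, 12 of 19 called lists held in TCD at 24 h and 11 of 23 in RWV. Between the vessels at 24 h 2 of 18 held, oxidative stress and gluconeogenesis and glycogen, and 0 held between the vessels at 4 h, in the interaction and in both comparisons of 4 h with fresh cells. By fry, 1 of 5 lists called between the vessels at 4 h passed, hypoxia and glycolysis, while ribosome biogenesis had an adjusted p of 0.0667, immediate early and periportal genes 0.118 each and the cytoskeleton 0.35. At 24 h 16 of 18 passed, without heat shock (0.0755) and ribosome biogenesis (0.0813). In the interaction 8 of 13 passed, without conjugation enzymes (0.0775), lipogenesis (0.0775), fatty acid oxidation (0.0892), the proteasome (0.0782) and Kupffer cell markers (0.225).

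**Figure D4:**
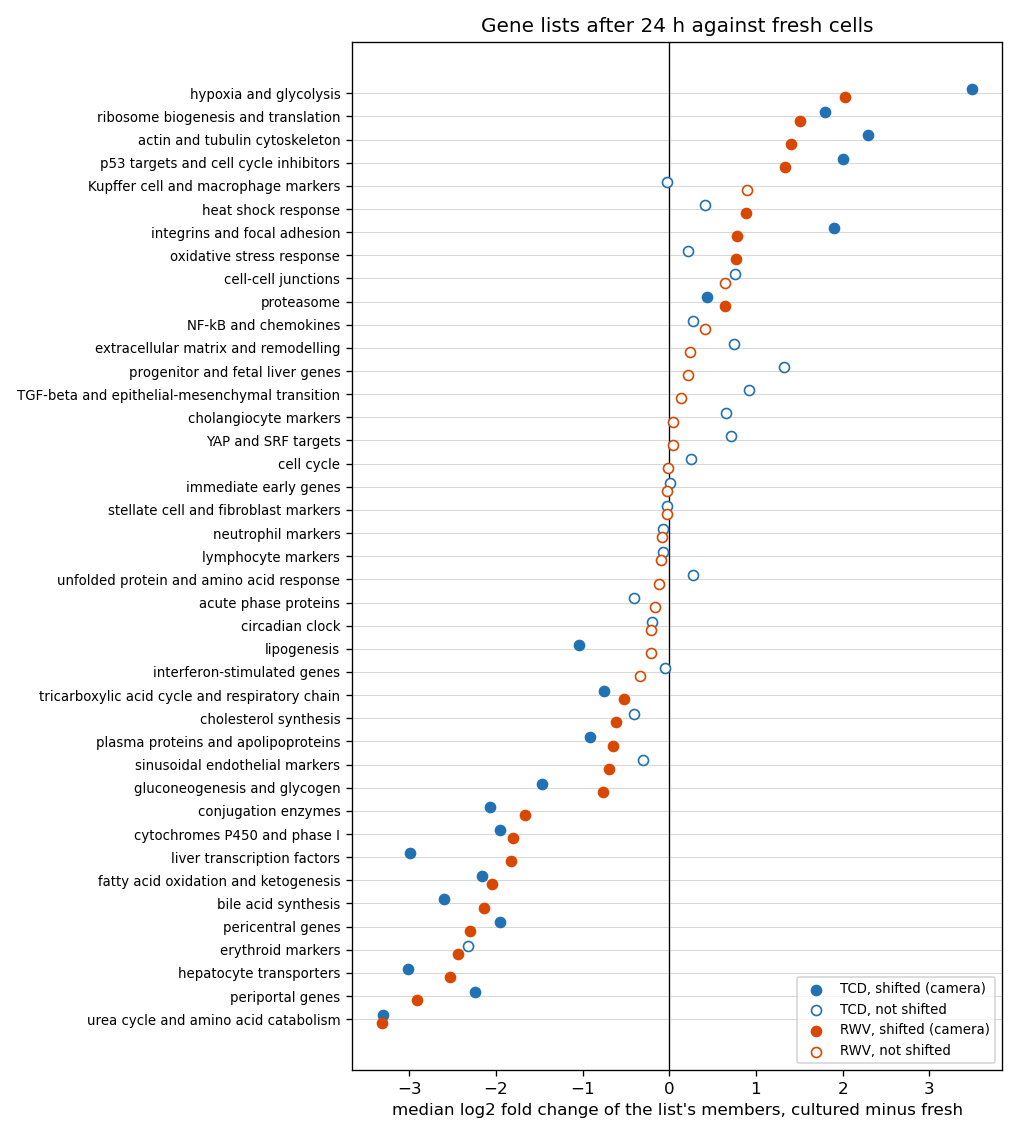
Median log2 fold change of each gene list after 24 h in culture, cultured minus fresh, for TCD and RWV (3 arrays per group); filled points mark lists that camera found shifted. The urea cycle lies lowest among the shifted pathways in RWV (-3.32) and in TCD (-3.31), and hypoxia and glycolysis highest (3.50 in TCD, 2.03 in RWV), while with arrays centred on reference genes the proteasome (-0.53 and -0.22) turns in both vessels, and integrins (-0.07) and oxidative stress (-0.09) turn in RWV.

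Between 4 h and 24 h, limma called 6904 genes in TCD (4481 higher at 24 h, 2423 lower; 4500 at least 2-fold, 3017 higher and 1483 lower, and 4588 higher and 8517 lower with no background filter) and 5164 in RWV (3282 higher, 1882 lower; 2984 at least 2-fold, 1772 higher and 1212 lower). Hnf4a fell in TCD (-2.40 ± 0.228, adjusted p = 2.7e-06) and RWV (-1.37 ± 0.228, adjusted p = 0.000413). Vim rose in TCD (6.27 ± 0.571) and RWV (6.58 ± 0.571), and Ccn2 rose in TCD (7.97 ± 0.622) and RWV (3.02 ± 0.622). Cyp1a1 rose in RWV (6.40 ± 0.424) and was not called in TCD (0.14, adjusted p = 0.782). Centred on reference genes, with the median of all genes at -0.73 and -0.44, the splits were 2136 higher and 6960 lower in TCD and 1816 higher and 5634 lower in RWV.

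Markers of other liver cells were followed beside these groups. The marker median of Kupffer cells was higher in RWV at 24 h by 0.87 ± 0.638 per array (n = 3, SD of the RWV arrays 1.08), with a two-sided exact permutation p of 0.4. Of 19 markers 8 were higher than in fresh cells in RWV and 0 lower, against 1 and 1 in TCD. The list was not called between the vessels (camera adjusted p = 0.0581), but its change with time was (median 0.84, adjusted p = 0.0153, 0.747 with an estimated correlation). That call ended without RWV replicate 1 (0.116) or TCD replicate 2 (0.0572) of 24 h. Cd68, a lysosomal protein gene of macrophages, was far above fresh cells in every culture, from 7.22 ± 0.156 in RWV at 4 h to 9.995 ± 0.156 in TCD at 24 h. It was lower in RWV than in TCD at 24 h (-1.21 ± 0.156).

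The cholangiocyte marker median was lower in RWV at 24 h by -0.60 ± 0.13 (two-sided exact permutation p = 0.1, the smallest possible). Sinusoidal endothelial markers (-0.02 ± 0.0129, exact p = 0.3) and stellate cell markers (0.02, exact p = 0.4) hardly differed between the vessels, though Stab2 (-2.36 ± 0.306) and Reln (-4.95 ± 0.420) were lower in RWV. Against fresh cells, endothelial markers were lower in RWV at 24 h, 0 higher and 7 lower of 17, with Dnase1l3 at -2.16 ± 0.173 (median -0.69, camera adjusted p = 0.0138, 0.35 with an estimated correlation). Erythroid markers were lower there too, 0 and 2 of 3, with Alas2 at -2.44 ± 0.129 (median -2.44, 0.0393, 0.0987 with an estimated correlation). The medians per array at 24 h were close in both vessels, so these falls were not particular to RWV. They were -2.45 in RWV and -2.33 in TCD for erythroid markers, and -0.30 and -0.28 for endothelial ones (exact permutation p = 0.3 for each). The erythroid call ended without TCD replicate 2 of 4 h (0.0522). At 4 h all 7 marker medians were lower in RWV, that of lymphocyte markers by -0.12 ± 0.119 (exact p = 0.4) and the other 6 with an exact p of 0.1 each. These 6 were the medians of endothelial (-0.23 ± 0.0814), stellate (-0.14 ± 0.0528), Kupffer (-0.16 ± 0.0771), cholangiocyte (-0.08 ± 0.013), neutrophil (-0.10) and erythroid (-0.16) markers. The cholangiocyte and neutrophil values are of the order of the difference in background between these arrays. That difference may also add to the other medians, which was not tested. No lymphocyte or neutrophil marker, of 3 measured for each, was called between the vessels.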

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

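The tests of the hypoxia and glycolysis list and of the liver transcription factors against matched lists, and the counts over other splits of the arrays, were planned. The count over all splits that part the arrays of each number and every other test in this part were chosen after the result was seen. The difference between the vessels changed with time for 1573 genes, by a test of that change itself. Of 100 drawn splits of the arrays 1 gave as many, the real one. Because arrays of 1 number resemble each other, all 32 splits that part every number between the vessels were counted too. Again 1 gave as many (3.12%), the smallest share that 32 splits allow. These splits also break the difference between the vessels at each time, so they cannot separate a change with time from a difference that stays. Among those that did not exchange whole groups the highest was 688. The highest of all other splits, with 1406, exchanged whole groups at 1 time and points to a structure of the samples, since it follows the difference between the vessels itself. The genes with the largest change with time were Cyp1a1 (6.252), Slc17a3 (5.437), N4bp2l1 (4.528), Hykk (4.515) and Baat (4.452) upwards, and Plod2 (-5.85), Serpinb9g (-5.537), Acta1 (-5.401), Lce1f (-5.296) and Nupr1 (-5.139) downwards. The lists whose change with time passed, none of which did with an estimated correlation, were conjugation enzymes (0.3519), transporters (0.3339), gluconeogenesis and glycogen (0.7441), lipogenesis (0.3952), fatty acid oxidation (0.6044), liver transcription factors (1.044), the tricarboxylic acid cycle (0.2115), oxidative stress (0.2711), the proteasome (0.1615) and Kupffer cell markers (0.8415) upwards, and the cytoskeleton (-0.3333), integrins (-0.348) and ribosome biogenesis (-0.5794) downwards. In probe sets that the comparisons do not use, the hybridisation controls of replicate 2 of TCD at 4 h had a median of 1.0836, above the other arrays.

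More genes were at least 2-fold higher than lower in RWV at 4 h, 90.17% of those called. Weak signal of replicate 2 of TCD was tested by leaving that array out, which kept the share at 83.73%, with 247 genes higher and 48 lower against 413 and 45. A scale difference between the arrays was tested by centring them on reference genes, which kept it at 78.87%, both above the 60% set as the limit after the data had been seen. Among all called genes, however, that centring took the share from 89.2% to 54.9%, so scale stays open as the source of the excess among smaller changes. More degraded RNA in TCD would widen the gap between the 3' and 5' control probe sets there. The gap in TCD minus that in RWV was 0.04808 with a standard error of 0.0314, below the limit of 0.3 set for it. For the genes changed at least 2-fold none of these, tested singly, reached the limit set for it. The fall from 413 to 247 higher genes leaves open that part of the excess rests on replicate 2 of TCD. Centring moves an array by 1 value, so it does not test a difference in spread. At 4 h the 95th percentile of the probe sets was 0.97 to 1.20 in RWV and 0.78 to 0.86 in TCD. The explanations were not tested together. A real early difference between the vessels remains a candidate explanation, as a hypothesis only.

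Hypoxia and glycolysis genes were lower in RWV at both times. If RWV had only changed less from fresh cells in all genes, lists matched on the mean change from fresh would shift alike, but their median was 0.1632 at 4 h and -0.2865 at 24 h, against -0.82 and -0.97. Without replicate 2 of TCD the list stood at -0.8947 at 4 h. Lower activity of hypoxia-inducible factors in RWV may explain the pattern, since the members outside glycolysis, which these factors also drive, had medians of -0.9443 and -0.9748. Of these 15 genes 4 were called lower at 4 h and 7 at 24 h, and at 24 h Adm (-0.32, adjusted p = 0.947) and Ankrd37 (-0.05, adjusted p = 1) were not. That test was run on the data in which the pattern was found, and oxygen was not measured here.

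Liver transcription factors were higher in RWV at 24 h. Lists matched on the mean change from fresh had a median of 0.1732, against 1.19, so a smaller change of all genes does not account for the whole. More cells of every other type in TCD would lower all hepatocyte genes there by about as much, but the upper quartile of the urea cycle and amino acid catabolism genes was only 0.2432 and their median -0.33. So this does not account for the whole either, though the median of plasma proteins per array was higher in RWV by 0.19 ± 0.0722, and a part stays open. The cholangiocyte marker median was lower in RWV (-0.60 ± 0.13). More cells of that type alone in TCD would also lower all hepatocyte genes there. The urea cycle values therefore argue against them as the whole explanation too, and a part stays open.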

How the results depend on the processing

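The stricter filter on the spread and the background correlation above 0.9 were chosen after the data had been seen, and all other tests here were planned. Where a value moved, the cause was not tested. With no filter on the background the calls were 6928 at 4 h between the vessels (1332 higher, 5596 lower), 3147 for the change with time (2043 up, 1104 down) and 13105 between 4 h and 24 h in TCD (4588 higher, 8517 lower), so that all 3 splits turned. There the cytoskeleton (-0.07739) and periportal genes (-0.1753) at 4 h turned up relative to the other genes. Fitted with only the arrays compared, 109 genes were called between the vessels at 4 h and 1532 in TCD at 4 h against fresh. With array weights the vessels differed in 1288 genes at 4 h and 3057 at 24 h, and 2761 changed with time. An adjusted p below 0.01 left 239 at 4 h, 1032 at 24 h, 597 with time, 1929 for TCD and 2308 for RWV at 4 h against fresh. Centring on reference genes called 7908 in RWV at 4 h against fresh and turned Psmd4 (-0.02166) and the proteasome (-0.5269) in TCD at 24 h. The mean of probe sets turned Cs (-0.003732) between the vessels at 24 h and Pde4b (0.3738) in TCD at 4 h. Without probe sets of shared sequence Tmsb10 turned in TCD at 24 h (-0.1825) and in RWV at 4 h (-0.03862) and 24 h (-0.1515). By fry 1 of 5 lists called between the vessels at 4 h, 16 of 18 at 24 h and 8 of 13 for the change with time passed, and the direction of immediate early genes (0.007456) and Kupffer markers (-0.02978) in TCD at 24 h turned, though camera called neither list. The difference in distance from fresh cells at 4 h, -0.01012, became 0.0512 as 1 minus Spearman's correlation and 0.005106 with the mean of probe sets. That at 24 h, -0.2467, was -0.006632 as 1 minus Spearman's correlation (exact p = 0.2). The correlation was taken with the mean of the fresh arrays after their median had been subtracted, so it does not measure closeness to fresh cells. With each array left out in turn the calls ran from 390 to 994 at 4 h and from 1234 to 2280 at 24 h, the distance at 4 h from -0.04314 to 0.02789 and that at 24 h from -0.2694 to -0.2014. With the replicate block, in which arrays of 1 number are treated as paired, 860 genes were called at 4 h and 2193 at 24 h. Of the results of named genes, counted once in each comparison, 880 were kept under the block, 7 were stronger and 6 weaker. The level filter of 6 was not run, because the values are relative to fresh cells and hold no level, which also means that signal over background was judged from the spread and the background profile alone. The robust prior gives no values for lists.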

Other observations

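The classes by symbol and the target genes in this part were chosen after the results had been seen, as were their tests, while the counts over other splits were planned. Zinc finger genes, which encode mostly repressors of transcription, were higher in RWV than in TCD at 4 h. Of 329 measured by symbol 75 were higher and 2 lower, with a median of 0.37 (camera p = 9.29e-11, 0.00636 with an estimated correlation), and without replicate 2 of TCD 50 were higher and 0 lower, with a median of 0.30. At 24 h 10 were higher and 11 lower, and the change with time was -0.43 (4 up and 59 down, camera p = 4.82e-06, 0.0358 with an estimated correlation). Against fresh cells 20 were higher and 65 lower in TCD at 4 h, and 86 higher and 27 lower in RWV at 4 h. With arrays centred on reference genes the median between the vessels at 4 h was 0.16 (51 higher, 7 lower) and the change with time -0.12 (20 up, 37 down). In RWV at 4 h against fresh cells 59 were higher and 119 lower. Such centring moves all genes of an array alike, so this turn is not particular to the class. Without ribosomal protein genes and Eef2 in the centring, the class median in that comparison was -0.39, against -0.54 for all genes. Centred without the ribosomal protein genes and Eef2 among the reference genes, the change with time turned to 0.10 (66 up, 32 down). The median of all genes was then 0.53, so the class stayed below the other genes. At 4 h between the vessels the class median was 0.10 (48 higher, 9 lower), against -0.28 for all genes.

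Genes of cytosolic ribosomal proteins rose in both vessels by 24 h relative to the other genes. Of 43 measured by symbol 40 were higher than in fresh cells in TCD and 39 in RWV, with 0 lower in either, and medians of 0.76 and 0.77 (camera p = 6.13e-11 and 1.19e-12, 0.0118 and 0.00755 with an estimated correlation). The reference genes hold 3 genes of this class, so the arrays were centred on the other 6 of them without Eef2. The medians were then -0.22 in TCD (7 higher, 16 lower) and 0.06 in RWV (13 higher, 4 lower), against -0.99 and -0.70 for all genes, so only the rise relative to the other genes held in both vessels. Between the vessels at 24 h 2 were higher and 1 lower. At 4 h 4 were higher than in fresh cells in TCD and 11 in RWV, again with 0 lower in either, though under that centring 20 were lower in RWV.

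Cyp1a1 was 6.20 higher in RWV at 24 h, and activation of the aryl hydrocarbon receptor there is a candidate explanation. Its other measured targets had a median of 0.1878, of which Nqo1 was higher (2.10 ± 0.266), while Cyp1a2 (0.19 ± 0.183, adjusted p = 0.613) and Tiparp (-0.45 ± 0.322, adjusted p = 0.442) were not called. With 1 of 3 higher the targets do not decide, and Nqo1 is also a member of the oxidative stress response list. A measurement of receptor binding, or the same cultures with a receptor antagonist, would decide between this and a regulation of Cyp1a1 alone.

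For comparisons of 3 against 3 arrays 10 splits are too few for a share under 0.05, so the counts are given as they stand, with the highest of the other splits after each. Between the vessels they were 766 and 3 at 4 h, and 1890 and 7 at 24 h. Against fresh cells they were 3164 and 13 for TCD at 4 h, 6981 and 0 for TCD at 24 h, 3670 and 3 for RWV at 4 h, and 6203 and 1 for RWV at 24 h. Between 4 h and 24 h they were 6904 and 1 in TCD and 5164 and 0 in RWV. In each, 1 split, the real one, called as many. A split that mixes the groups compared moves their difference into the spread, which lowers its count where the groups differ. The counts of the other splits therefore do not give the number of calls expected by chance.

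The lower hypoxia and glycolysis genes in RWV may follow from oxygen supply, as the members outside glycolysis (-0.9443 at 4 h and -0.9748 at 24 h) would require. Of these 15 members, however, 11 were not called at 4 h and 8 were not called at 24 h. Oxygen tension measured in both vessels, or monolayers kept at a higher oxygen tension, would test this. The higher liver transcription factors might instead depend on cell contact, which lists matched on the change from fresh (0.1732) do not address. Aggregates formed without rotation would separate contact from the vessel, since the series changes both together.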
